A study of Bos taurus with 28 samples.

How the data were processed

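circRNAs were profiled in liver and rumen of 3 steers with up to 6 enrichment methods. Total RNA was extracted with the mirVana kit and libraries were made with the TruSeq Stranded Total RNA kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.9a and bedtools 2.30.0, and the genome builds ARS-UCD1.2 (cattle) and GRCh38.p13 (human), without saying which step used which build; the program that called circRNAs is not given in the sources used here. Coordinates are printed as the deposited table gives them, with starts counted from 1. The chromosome names are those of cattle, and the build behind them is not stated. No genome sequence was used here.

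The deposited data are 1 table of 50837 circRNAs with whole-number counts of BSJ reads per library, not normalized, with a host gene symbol, a transcript, exon sizes and a type for each circRNA, as the authors deposited them. Of the circRNAs, 48914 are typed as exonic and 1923 as intronic. The table holds 28 columns of this series and 5 columns of other libraries, which were not used here. Of all circRNAs, 1437 have no read in the libraries used, 34 lie on unplaced scaffolds, 1 is mitochondrial and 1087, with 1.788% of reads, have no gene symbol. The latter stayed in library totals and circRNA tests and out of host-gene sums. Exon-size lists of 14550 circRNAs had lost their separators and were read again as sizes of 3 digits each, and those of 2160 could not be read and have no spliced length. Total sequencing depth is not known, only BSJ totals, so a difference in BSJ reads between methods mixes the share of circRNA in a library with how deeply it was sequenced.

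Libraries were grouped by tissue and method from the labels. Replicate libraries of a group were compared by chi-square tests on circRNAs with at least 10 reads per pair, and all pairs differed beyond sampling noise (chi-square per degree of freedom of 1.75 to 3.56), so none was counted as a duplicate. Groups with 1 library are given as values. The groups, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where stated.

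For each library, BSJ reads, circRNAs detected with at least 2 reads, circRNAs at equal reads (the expected number in a subsample of 6049 reads, the smallest total among the 24 libraries of the 4 shared methods) and the share of intronic reads were computed. The number at equal reads counts circRNAs with at least 1 read in the subsample, not at least 2. Means of log2 values, or of percentages for the share, were compared by two-sided exact permutation within tissue for methods, where 400 assignments exist, and within method for tissues, where 160000 exist. Benjamini-Hochberg adjustment ran over 12 tests, and over 4 for the intronic share. Wilson intervals at 95% are given for shares of single libraries. A fold against a group with 0 reads is a lower bound against 3 reads over the group, the smaller of the values with TMM-scaled and with unscaled totals. With 1 to 3 reads, a ratio of reads per total with an exact binomial interval is given, with TMM-scaled totals for host genes and unscaled totals for circRNAs between methods.

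Single circRNAs were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling on BSJ totals) in R 4.3.3, in 1 fit per tissue over its replicated groups and 1 joint fit, on circRNAs with at least 5 reads in at least 3 libraries of the fit. This left 1334 circRNAs in liver (55.8% of reads), 1107 in rumen (47.5%) and 1842 jointly (55.9%). The tissue contrast averages the 4 shared methods with equal weight, and interactions are liver differences minus rumen differences. Host genes were tested on summed reads, which left 2053 (86.9% of reads). Calls have a Benjamini-Hochberg adjusted p under 0.05. CPM in these comparisons use TMM-scaled totals, while CPM of the most abundant circRNAs, of single libraries and of the plot of 4 circRNAs use unscaled totals. The 15 gene lists were written from textbook knowledge, and those with at least 5 measured hosts were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. They are hepatocyte secreted proteins; urea cycle and amino acid catabolism; liver lipid, bile acid and xenobiotic metabolism; stratified squamous epithelium; short-chain fatty acid use, ketogenesis and epithelial transport; smooth muscle; fibroblast and extracellular matrix; endothelium; immune cells; bile duct epithelium; widely studied circRNA hosts; cytosolic ribosomal proteins; small structured RNAs; mitochondrially encoded genes; and circRNA biogenesis and turnover factors. Summed reads of a host gene do not separate its circRNAs from one another, and reads that match near-identical gene copies may have been assigned to either.

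Named items follow a rule. For the tissue comparison they are host genes with a symbol, past the threshold, at least 2-fold apart and pointing the same way in every method, the 10 with the highest mean CPM in each direction, and in each list the up to 4 members with the smallest adjusted p. For method comparisons they are the up to 4 circRNAs with the smallest adjusted p in each direction. The 5 circRNAs with the highest mean CPM per tissue, the 5 with most reads in the liver Ribo library and members of the widely studied list complete the rule. A few items that the rule selects are not reported here.

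The edgeR tests between methods and between tissues were run on simulated data drawn from the real means and library sizes with 200 changed items. For liver Ribo-R against R (1334 circRNAs), 2.99% of 2-fold, 31.3% of 4-fold and 66.7% of 8-fold changes were recovered. For rumen Ribo-R against R (1107) these were 4.48%, 28.4% and 60.6%. For host genes between tissues (2053) they were 44.8%, 89.6% and 100%. At most 4.88% of the calls in any comparison were false. Alternatives were RLE size factors or no scaling factor, no filter or 10 reads in 3 libraries, DESeq2 1.42.0, the replicate number as a block, fits of the 2 compared groups alone, other detection thresholds and depths, fry or an estimated correlation for lists, and each library left out in turn. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.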

Results

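Circular RNAs (circRNAs) were measured by RNA sequencing in liver and in rumen, the largest forestomach compartment of cattle, from 3 Kinsella Composite steers sampled at 15 months of age. A circRNA forms when a downstream splice site is joined to an upstream one, and each was counted by the reads that cross this back-splice junction (BSJ). The libraries differed in how linear RNA was removed. R libraries were made from RNA digested with RNase R, an exonuclease that degrades linear RNA and spares closed circles. RTP libraries had RNase R digestion followed by tailing of leftover RNA with poly(A) and removal of the tailed molecules. Ribo-R libraries had ribosomal RNA (rRNA) removed before RNase R, Ribo-RP libraries then had poly(A) RNA depleted, and Ribo-RTP libraries had both the tailing and the depletion after rRNA removal and RNase R. A Ribo library had rRNA removal alone. Each tissue had 3 R, 3 RTP, 3 Ribo-R and 3 Ribo-RP libraries. Liver also had 2 Ribo-RTP libraries and 1 Ribo library, and rumen had 1 Ribo-RTP library, so that 28 libraries were used. They held 501827 BSJ reads over 49400 circRNAs, from 2153 reads in the liver Ribo library to 28966, and 19441 of these circRNAs (39.4%) had a single read over all libraries. The labels do not say which steer gave which library, so p-values measure only the spread between these libraries, and intervals and floors cover counting error only.

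The first question was how rRNA removal before RNase R changes the yield of circRNAs. Ribo-R libraries gave 25852 ± 3999 BSJ reads (SD, n = 6) against 10891 ± 2914 in R libraries (n = 6). The geometric means, which all folds of yield compare, differed 2.43-fold, and 2.13-fold in liver and 2.77-fold in rumen. In liver the R libraries held 12661 ± 2180 reads and the Ribo-R libraries 26724 ± 1252 (n = 3 each). In rumen these values were 9121 ± 2660 and 24979 ± 6011 (n = 3 each). The number of circRNAs detected with at least 2 reads was 2.08-fold higher, at 3964 ± 530 against 1933 ± 419 per library (n = 6 each). Total sequencing depth is not known, so these differences in reads and detected circRNAs mix the share of circRNA with how deeply libraries were sequenced. When every library was reduced to 6049 reads, 3388 ± 146 circRNAs were found in Ribo-R and 3124 ± 143 in R libraries, a 1.08-fold difference. The count at equal reads includes circRNAs with a single read. Its fold is therefore not that of the count with at least 2 reads at equal depth. All 3 measures were higher in 6 of 6 pairs of libraries with the same tissue and number, and the exact two-sided permutation test within tissue (n = 6 each) gave p = 0.005, the smallest possible, and an adjusted p of 0.015 over 12 tests for each. If the numbers do mark pairs, a sign-flip test of the paired differences can be used. This test takes the pairs of both tissues as independent, although they come from 3 steers. It gave its smallest possible p, 0.03125, and missed the threshold, with an adjusted p of 0.0938 for each measure. No difference between the tissues in these effects passed the permutation tests of the difference (adjusted p of 0.8, 0.8 and 0.833).

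Adding a poly(A) step to RNase R did not change the yield beyond the spread between libraries. RTP libraries gave 13481 ± 4499 reads and 2364 ± 650 detected circRNAs (n = 6), with geometric means 1.21-fold and 1.2-fold those of R libraries (exact permutation, n = 6 each, adjusted p = 0.587 for both). At equal reads the ratio was 0.993. One library, liver RTP replicate 3 with 6078 reads, decided this outcome: without it the log2 difference from R was 0.53 for reads (exact permutation, adjusted p = 0.0343) and 0.47 for detected circRNAs (adjusted p = 0.03), and the difference at equal reads turned positive, to 0.053. It also turned positive, to 0.016, without rumen R replicate 1. Ribo-RP libraries gave 24159 ± 2933 reads, 3836 ± 348 detected circRNAs and 3352 ± 135 at equal reads (n = 6), with geometric means 0.939-, 0.972- and 0.989-fold those of Ribo-R (exact permutation, n = 6 each, adjusted p of 0.587, 0.714 and 0.587). The log2 difference in detected circRNAs changed sign, to between 0.00043 and 0.014, when rumen Ribo-R replicate 1, rumen Ribo-R replicate 3 or rumen Ribo-RP replicate 2 was left out. The liver Ribo-RTP libraries had 21490 ± 77.1 reads and 3553 ± 44.5 detected circRNAs (n = 2). The rumen Ribo-RTP library had 10401 reads and 2099 detected circRNAs, and the liver Ribo library had 305 detected circRNAs.

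Rumen libraries spread their reads over more circRNAs than liver libraries. At equal reads, 3356 ± 179 circRNAs were found in rumen and 3134 ± 227 in liver (n = 12 each), so that the geometric mean in liver was 0.932-fold that in rumen, and liver was higher in 1 of 12 same-method pairs (permutation within method over all assignments, two-sided p = 0.000275, adjusted p = 0.0033). The 12 libraries of each tissue come from 3 steers, so they are not 12 independent animals, although the test takes them as independent. BSJ reads were 19708 ± 7481 in liver and 17484 ± 7605 in rumen, and detected circRNAs 3059 ± 1001 and 2989 ± 1086, differences within the spread (permutation, adjusted p of 0.587 and 0.835). Without liver RTP replicate 3 the difference in reads passed the test (log2 of 0.32, adjusted p = 0.0191). The small difference in detected circRNAs turned negative, to between -0.020 and -0.0016 on the log2 scale, when liver RTP replicate 1, liver RTP replicate 2, rumen R replicate 2 or rumen Ribo-R replicate 2 was left out.

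**Figure D1:**
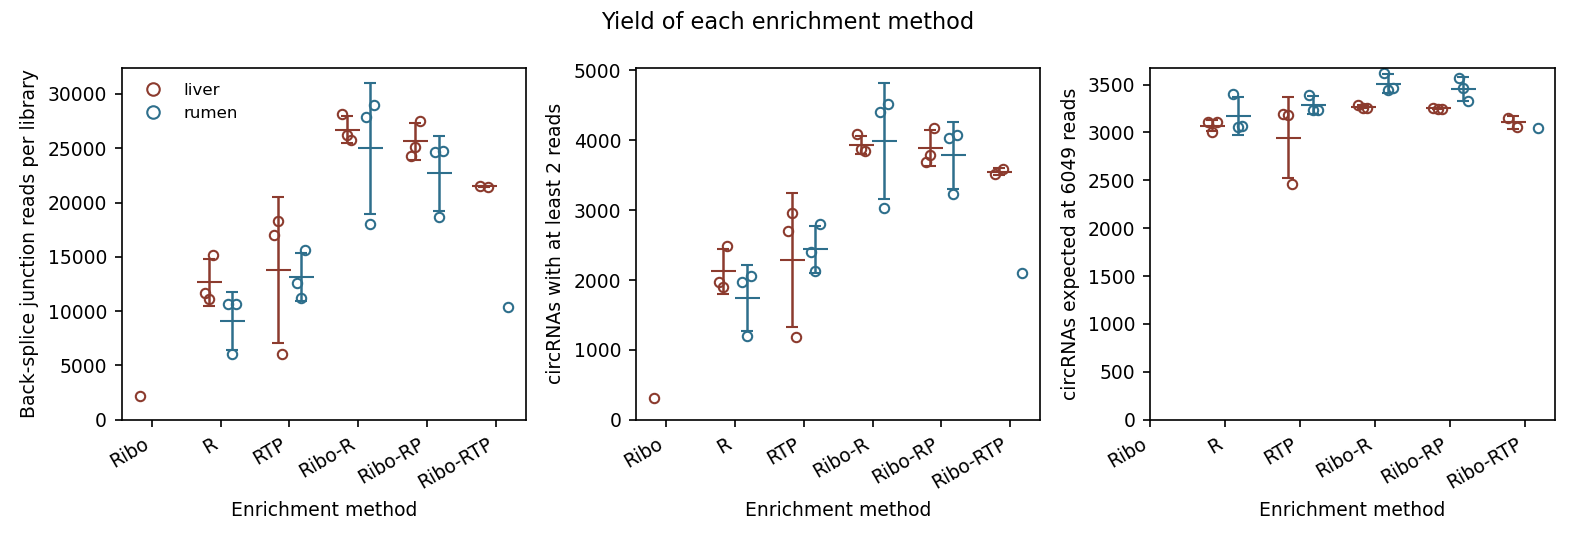
BSJ reads, circRNAs with at least 2 reads and circRNAs expected with any read at 6049 reads, per library, by enrichment method, for liver and rumen. Points are libraries, and horizontal marks with bars are means with SD where a group has at least 2 libraries; the geometric mean of Ribo-R libraries, which is not drawn, is 2.43-fold that of R libraries in reads and 1.08-fold at equal reads.

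Between 9.77% and 18.7% of the circRNAs detected in any library of a method were detected in all 3 of its libraries, with no test of the differences. In liver this share was 18.7% (1426 of 7608) for Ribo-R, 17.2% (1320 of 7666) for Ribo-RP, 14.6% (637 of 4353) for R and 10.3% (500 of 4857) for RTP. In rumen it was 16.0% (1273 of 7956), 14.9% (1155 of 7744), 9.77% (375 of 3840) and 11.9% (626 of 5270). With all libraries thinned to 6049 reads the shares drew closer, to 15.6%, 15.1%, 14.2% and 11.5% in liver and 13.6%, 11.4%, 9.65% and 10.2% in rumen.

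Intronic circRNAs, which come from spliced introns and include lariats, were a small part of every library. They held 0.972 ± 0.215% of BSJ reads in R libraries and 0.608 ± 0.155% in Ribo-R libraries (n = 6 each), lower in 6 of 6 such pairs after rRNA removal, a difference of -0.36 percentage points (exact two-sided permutation, p = 0.015, adjusted p = 0.03 over 4 tests). RTP libraries held 1.16 ± 0.645%, a difference of 0.19 points from R (exact permutation, n = 6 each, adjusted p = 0.68), and Ribo-RP libraries held 0.837 ± 0.353%, a difference of 0.23 points from Ribo-R (exact permutation, n = 6 each, adjusted p = 0.193). Liver libraries held 1.06 ± 0.489% against 0.728 ± 0.258% in rumen (n = 12 each), higher in 11 of 12 pairs (permutation, p = 0.0124, adjusted p = 0.03). Liver RTP replicate 3 had the highest share, 2.44% (95% Wilson interval 2.08 to 2.85%), and without it the RTP difference turned negative, to -0.041 points. Both passing differences were close to the threshold. With same-numbered libraries taken as pairs, a sign-flip test gave an adjusted p of 0.0625 for Ribo-R against R and 0.041 for the tissues. That test takes all pairs as independent, although they come from 3 steers. Its result for the tissues therefore does not measure the spread between steers. When single libraries were left out, the Ribo-R difference ranged from -0.44 to -0.33 points and missed the threshold in 9 of 12 cases, without liver R replicates 2 or 3, rumen R replicate 3 or any Ribo-R library of either tissue. The tissue difference ranged from 0.22 to 0.41 points and missed the threshold in 11 of 24 cases, which left out liver R replicates 2 or 3, liver Ribo-R replicates 2 or 3, liver Ribo-RP replicate 1, rumen R replicate 3, any rumen RTP library or rumen Ribo-R replicates 2 or 3. The Ribo-RP difference passed it without rumen Ribo-RP replicate 3 (0.33 points, exact permutation, adjusted p = 0.03). Counted only over circRNAs with at least 5 reads in at least 3 libraries, the Ribo-R difference was -0.22 points (adjusted p = 0.1) and the tissue difference 0.0021 points (adjusted p = 0.992). As a share of detected circRNAs, the Ribo-R difference was -0.34 points (exact permutation, adjusted p = 0.14) and the tissue difference 0.47 points (permutation, adjusted p = 0.0017). The liver Ribo library held 0.929% (20 reads, Wilson interval 0.602 to 1.43%) and the rumen Ribo-RTP library 1.03% (0.852 to 1.24%).

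In liver, a few circRNAs were lower and others higher when rRNA was removed before RNase R. The 3-exon circRNA of ARID1A, a subunit of the SWI/SNF chromatin remodelling complex (chromosome 2, 126448967 to 126452456, minus strand, 783 nt), fell from 4591 ± 898 CPM (BSJ reads relative to the scaled library total) in R libraries to 346 ± 166 in Ribo-R libraries (n = 3 each; log2 difference -3.70, SE 0.41, edgeR's quasi-likelihood test, adjusted p = 5.0e-16). The 3-exon circRNA of PROX1, a transcription factor of hepatocytes (chromosome 16, 69562359 to 69577209, minus strand), fell from 6573 ± 1998 to 1199 ± 153 CPM (-2.45, SE 0.34, adjusted p = 2.12e-10). An 8-exon circRNA of the chromatin organizer SATB1 (chromosome 1, 155464769 to 155507796, minus strand) fell from 1254 ± 727 to 89.0 ± 55.5 CPM (-3.68, SE 0.68, adjusted p = 2.24e-05), and one of the Polycomb-related gene SFMBT2 (chromosome 13, 16403706 to 16413276, plus strand) fell from 874 ± 292 to 112 ± 163 CPM (-2.88, SE 0.66, adjusted p = 0.00339). The 3-exon, 297 nt circRNA of LARP1B, an RNA-binding protein of the La-related family (chromosome 17, 29650713 to 29653374, minus strand), rose from 1201 ± 835 to 4263 ± 241 CPM (1.82, SE 0.37, adjusted p = 0.000282). A circRNA of PHF3, an RNA polymerase II-binding protein (chromosome 9, 634609 to 644205, plus strand), rose from 2 to 46 reads, a ratio of 10.9 (counting interval 2.85 to 92.7, adjusted p = 0.0479). With SCMH1, a Polycomb gene outside the rule for named circRNAs and named after its value was seen (chromosome 3, 105148218 to 105152405, plus strand, -1.87, adjusted p = 0.0232), 7 of 1334 tested circRNAs changed, 2 upward and 5 downward. The count was 4 without liver R replicate 3 or without liver Ribo-R replicate 3, and 2 with no filter on low counts, where LARP1B, PHF3, PROX1, SFMBT2 and SCMH1 no longer passed. LARP1B missed the threshold without liver R replicate 1 (log2 of 1.39). SFMBT2 missed it without liver R replicate 3 (-2.58), liver Ribo-R replicate 2 (-2.34) or liver Ribo-R replicate 3 (-2.55). PHF3 missed it under every alternative scaling, filter and test and without any R library or liver Ribo-R replicates 2 or 3 (2.90 to 3.81).

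In rumen the same ARID1A and LARP1B circRNAs changed in the same directions. ARID1A fell from 3896 ± 1498 to 334 ± 177 CPM (n = 3 each; -3.60, SE 0.43, edgeR's quasi-likelihood test, adjusted p = 6.46e-10), and LARP1B rose from 586 ± 667 to 5982 ± 1812 CPM (3.21, SE 0.44, adjusted p = 3.96e-08). A pair of circRNAs of ARHGAP5, a GTPase-activating protein, had no read in R libraries. The 1-exon, 3888 nt circRNA (chromosome 21, 42518712 to 42522599, plus strand) reached 1247 ± 573 CPM in Ribo-R, at least 10.1-fold higher (adjusted p = 3.0e-05), and the 2-exon circRNA ending at 42547435 reached 873 ± 86.3 CPM, at least 7.55-fold higher (adjusted p = 0.000715). A circRNA of the chromatin remodeller ATRX (chromosome X, 74724236 to 74749815, plus strand) also went from 0 reads to 713 ± 223 CPM, at least 6.45-fold higher (adjusted p = 0.00572). Bounds are set against 3 reads over the group. Downward changes were in HECW2, a ubiquitin ligase (chromosome 2, 84793067 to 84821788, minus strand, 1209 ± 250 to 168 ± 21.7 CPM, -2.80, SE 0.65, adjusted p = 0.00574), FBRS (chromosome 25, 26788579 to 26790847, plus strand, 18 reads to 0, at least 16.0-fold lower, adjusted p = 0.00708) and a 1-exon, 186 nt circRNA of C16H1orf116 (chromosome 16, 4839835 to 4840020, minus strand, 2834 ± 1035 to 984 ± 389 CPM, -1.50, SE 0.38, adjusted p = 0.0169).

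Of 1107 circRNAs tested in rumen, 14 changed between Ribo-R and R, 10 upward and 4 downward. The 6 others, all higher in Ribo-R and named after their values were seen, came from DCUN1D4 (log2 difference 2.02), SENP6 (1.37), SMARCA5 (1.32), KIAA2026 (at least 6.21-fold), GCFC2 (at least 4.38-fold) and PHF3 (54 against 2 reads, ratio 9.86, interval 2.60 to 83.5). The count was 9 without rumen R replicate 3 and 7 without rumen Ribo-R replicate 3, where HECW2 (-2.71) and FBRS missed the threshold. C16H1orf116 missed it without rumen R replicate 1 (-1.12), rumen Ribo-R replicate 1 (-1.54) or rumen Ribo-R replicate 2 (-1.25). DESeq2 called 5, among which LARP1B, FBRS and C16H1orf116 were missing. With the replicate number as a block the count rose to 25, 18 upward and 7 downward, with all 14 among them. The median of all tested circRNAs was 0.27 above R with TMM scaling, 0.16 with RLE size factors and 0.12 with BSJ totals alone, so changes near that size depend on the scaling. Among the 646 circRNAs tested in both tissues, LARP1B and PHF3 were higher in both, where independent lists would share 0.0248, and ARID1A was lower in both, against 0.0031. No libraries are shared between the 2 tissues.

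**Figure D2:**
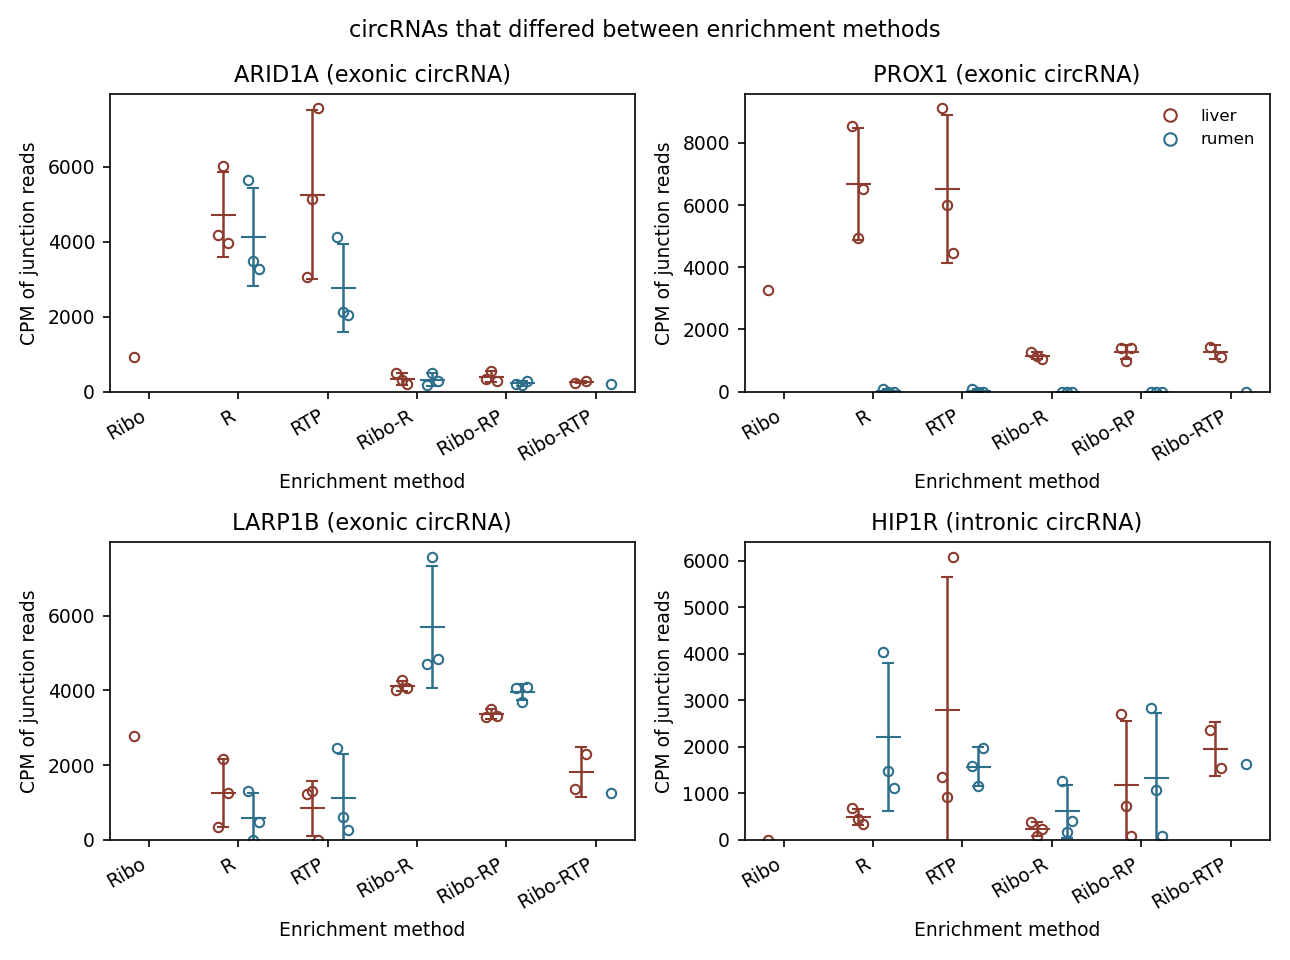
CPM of BSJ reads, on unscaled totals, of the ARID1A, PROX1, LARP1B and HIP1R circRNAs in every library, by enrichment method and tissue. Points are libraries, and marks with bars are means with SD where a group has at least 2 libraries. ARID1A reaches at most 558 CPM in libraries with rRNA removal and RNase R and at least 2048 CPM in R and RTP libraries, while HIP1R varies widely between libraries of 1 method.

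The poly(A) steps changed few circRNAs, and in liver the 2 that rose were intronic. A 185 nt intronic circRNA of HIP1R, a clathrin- and actin-binding protein (chromosome 17, 52675154 to 52675338, minus strand), rose from 479 ± 187 CPM in R to 2355 ± 2038 in RTP libraries (n = 3 each; 2.20, SE 0.50, edgeR's quasi-likelihood test, adjusted p = 0.0143), and was the only 1 of 1334 called between these methods. It rose from 241 ± 165 CPM in Ribo-R to 1220 ± 1455 in Ribo-RP libraries (n = 3 each; 2.27, SE 0.48, adjusted p = 0.00381) and to 2043 ± 706 in Ribo-RTP libraries (n = 2; 3.03, SE 0.51, adjusted p = 2.98e-06), comparisons that share the Ribo-R libraries. A 120 nt intronic circRNA of ATXN2L, a stress granule protein (chromosome 25, 25975390 to 25975509, minus strand), rose from 3 to 32 reads between Ribo-R and Ribo-RP, a ratio of 11.1 (interval 3.48 to 56.7, adjusted p = 0.0351). The HIP1R reads of single libraries, replicates 1 to 3, were uneven: 23, 17 and 37 in RTP and 66, 18 and 2 in Ribo-RP. Rumen Ribo-RP libraries fell in the same order, with 70, 20 and 2 reads. ATXN2L did so too, with 20, 9 and 3 reads in liver and 14, 4 and 1 in rumen Ribo-RP. In RTP libraries HIP1R had 20, 13 and 31 reads in rumen, another order, which liver shared. In Ribo-R libraries the tissues also shared an order, with 11, 2 and 6 reads in liver and 35, 3 and 12 in rumen. The cause of these orders was not tested. The RTP call ended without liver RTP replicate 3 (log2 of 1.37), liver R replicate 2 (2.06) or liver R replicate 3 (2.01), and the count was 2 without liver RTP replicate 1. The Ribo-RP call of HIP1R ended without liver Ribo-RP replicate 1 (0.69), liver Ribo-R replicate 2 (1.80) or liver Ribo-R replicate 3 (2.22). That of ATXN2L ended without any Ribo-R library (3.25 to 3.30) or without Ribo-RP replicates 1 or 2 (2.43 and 3.40). The Ribo-RTP call stayed when any single library was left out, although without 1 of the 2 Ribo-RTP libraries the spread comes from the other groups, and none of these calls was made by DESeq2 or with a filter of 10 reads.

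In rumen 1 circRNA, of KIAA2026, fell from 51 reads in Ribo-R to 1 in Ribo-RP libraries, a ratio of 46.3 (interval 7.95 to 1864; log2 of -4.95, SE 1.06, edgeR's quasi-likelihood test, adjusted p = 0.0114), and it is the same circRNA (chromosome 8, 38717330 to 38741975, plus strand) that was higher in Ribo-R than in R. Both comparisons use the same Ribo-R libraries. In liver, where it was not called and no library is shared with rumen, this circRNA had 25 reads in Ribo-R, 0 in Ribo-RP and 2 in Ribo-RTP libraries. The rumen call ended without rumen Ribo-RP replicate 1 (log2 of -4.46) or replicate 3 (-4.44), the count was also 0 without rumen Ribo-R replicates 1, 2 or 3, and DESeq2 did not make it. Between RTP and R in rumen, edgeR called 0 of 1107 circRNAs, with 54 at an unadjusted p under 0.05, and DESeq2 called 0. Simulated 4-fold changes were recovered in 26.9% of cases for that comparison and 8-fold ones in 65.2%.

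Liver and rumen differed in many circRNA host genes, led in liver by PFKFB1. Over the 4 shared methods (n = 12 libraries per tissue), circRNAs of PFKFB1, the liver enzyme that sets fructose 2,6-bisphosphate, reached 25392 ± 2828 CPM in liver and 2 reads in rumen, a ratio of 2816 (interval 779 to 23258; edgeR's quasi-likelihood test, adjusted p = 1.05e-123). ALB, the albumin gene, had 1132 liver reads against 1 (ratio 1200, 215 to 47445) and PROX1 761 against 2 (ratio 403, 111 to 3337). SLC41A2, a magnesium transporter, reached 11581 ± 3073 against 79.3 ± 53.2 CPM (log2 difference 7.26). SCP2, a peroxisomal sterol carrier (5.29), CAT, catalase (5.17), RMDN2 (4.87), SC5D of cholesterol synthesis (4.15), NADK2, the mitochondrial NAD kinase (4.09), and GK5, a glycerol kinase-like protein (3.95), completed the 10 liver-high host genes with the highest mean CPM among those at least 2-fold apart and higher in all 4 methods.

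Host genes with more circRNA reads in rumen included SLC9A2 and A2ML1. SLC9A2, a sodium-proton exchanger of epithelia, reached 5087 ± 2270 CPM in rumen, with 1074 reads against 3 in liver (ratio 338, interval 115 to 1640.0). A2ML1, a protease inhibitor of stratified epithelia, reached 3497 ± 711 CPM from 778 reads against 0, at least 242-fold higher in rumen. The log2 differences, liver minus rumen, were -5.20 for the phosphatase PTPN13, -4.97 for HECW2, -3.30 for GFRA2, a receptor subunit for neurturin, -2.24 for the kinase SLK, -2.16 for GNPTAB of lysosomal enzyme sorting, -1.34 for PCNX1, -1.14 for H2AFY, which encodes a macroH2A histone, and -1.05 for ZBTB44. In all, edgeR's quasi-likelihood test called 1010 of 2053 host genes, 558 higher and 452 lower in liver, and 935 of 1842 circRNAs, 514 higher and 421 lower. The median host gene lay at 0.04 with TMM scaling and at -0.21 with BSJ totals alone, which gave 481 higher and 577 lower, so the split between directions depends on the scaling. Without liver RTP replicate 3 and rumen R replicate 2, which held the fewest reads and were left out after seeing the data, 1000 host genes were called, 963 of them shared.

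Host genes of liver functions rose together in liver. All 19 measured hosts of the hepatocyte secreted protein list were higher (19 adjusted over the list alone; camera with a preset correlation, adjusted p = 1.32e-15, and 0.000353 with an estimated correlation). They included ALB and the complement genes C5 (889 against 1 read, ratio 943, interval 169 to 37269) and C3 (at least 174-fold). All 13 measured hosts of urea cycle and amino acid catabolism were higher (13 adjusted over the list alone; adjusted p = 3.96e-08, and adjusted p = 0.000159 with an estimated correlation), among them CPS1, the entry enzyme of the urea cycle (at least 93.2-fold), HPD of tyrosine breakdown (5.81) and DMGDH of choline breakdown (at least 59.9-fold). Of 19 hosts of liver lipid, bile acid and xenobiotic metabolism, 18 were higher (18 adjusted over the list alone; adjusted p = 4.17e-09, and 0.000417 with an estimated correlation), with SCP2, the phospholipid exporter ABCB4 (482 against 1 read, ratio 511, 91.3 to 20225), AOX1 (4.28) and the bile acid receptor NR1H4 (at least 47.4-fold), and HADHA at 0.35 did not pass. Summed reads of hepatocyte secreted hosts in rumen stood at 0.413% (interval 0.256 to 0.632%) of the liver level, and those of squamous hosts in liver at 9.0% of the rumen level. In camera with the preset correlation, 53 of 100 splits of the libraries between the tissues, the real split included, gave at least 4 lists. Its p-values may thus be too small. With the estimated correlation only the real split gave 4.

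Hosts of stratified squamous epithelium, the lining of the rumen, were lower in liver in 12 of 13 cases (12 adjusted over the list alone; camera, adjusted p = 4.17e-09, and 0.000353 with an estimated correlation). They included the epithelial transcription factor GRHL2 (at least 70.5-fold lower), the hemidesmosome and laminin genes ITGB4 (-3.64) and LAMA3 (-5.87), and the desmosomal cadherin DSC3 (at least 62.5-fold lower), and DST did not pass. The list of short-chain fatty acid use, ketogenesis and epithelial transport split, with 3 higher and 4 lower of 8 (the same adjusted over the list alone; camera, adjusted p = 0.269, and 0.39 with an estimated correlation). The self-contained fry test did call this list, with an adjusted p of 5.4e-05. ACSS3, an acyl-CoA synthetase, was higher in liver (686 against 1 read, ratio 727, 130.1 to 28768). SLC9A2 and PPARG (1 against 185 reads, ratio 174.5, 30.9 to 6929) were lower. Of 5 smooth muscle hosts, 2 were higher, MYLK (3.58) and LPP (1.2), and 1 lower, ITGA8 (-3.21) (3 and 1 adjusted over the list alone; adjusted p = 0.767, and 0.812 with an estimated correlation).

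Among hosts of widely studied circRNAs, 6 of 29 were higher and 8 lower in liver (the same adjusted over the list alone; camera, adjusted p = 0.387, and 0.638 with an estimated correlation). PSD3 (3.70) and FNDC3B (2.41) were higher, and BNC2 (-4.49), CAMSAP1 (-1.97), ZNF609 (-1.40) and FOXP1 (-1.39) lower, whereas HIPK3 (-0.34, adjusted p = 0.0787), SMARCA5 (0.27, adjusted p = 0.208) and FOXO3 (0.16) did not pass. Of 13 hosts among circRNA biogenesis and turnover factors, 2 were higher and 7 lower (the same adjusted over the list alone; adjusted p = 0.0692, and 0.113 with an estimated correlation). The self-contained fry test did call this list, with an adjusted p of 2.86e-06. The RNA-binding protein QKI was higher (1.69), and the splicing regulators MBNL2 (-3.77) and ESRP1 (at least 20.6-fold lower) and the m6A reader YTHDF2 (3 against 63 reads, ratio 19.8, interval 6.48 to 98.6) were lower. ESRP1, ESRP2, MBNL1 and QKI stand in 2 lists each.

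Lists with under 5 measured hosts were not tested as lists. Of fibroblast and matrix genes, FN1 was at least 20.9-fold higher in liver and LAMA2 lower (-3.02), and COL14A1 at -0.81 did not pass. It passed without liver Ribo-RP replicate 2 (-1.34) and turned to 0.33 without rumen R replicate 3. Of endothelial genes, STAB2, a scavenger receptor of liver sinusoids, was at least 27.7-fold higher and MECOM lower (ratio 55.65, interval 9.61 to 2235). Of immune genes, DOCK2 (2.32) and the macrophage receptor MRC1 (ratio 12.2, interval 3.01 to 107) were higher and DOCK8 lower (-1.71). DOCK2 missed the threshold with DESeq2 and without liver R replicate 3 (1.44), liver RTP replicate 3 (1.89) or liver Ribo-RP replicate 2 (1.99), and MRC1 with DESeq2 and without liver R replicate 3 (2.31) or liver RTP replicate 1 (2.33). The bile duct genes PKHD1 (at least 36.0-fold) and ANXA4 (1.46) were higher. Of 79 ribosomal protein genes 1 was measured, RPL17, which was lower (ratio 10.7, interval 3.36 to 54.4). Adjusting over each of these lists alone gave the same calls. No host of the small structured RNA or mitochondrial lists was measured.

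**Figure D3:**
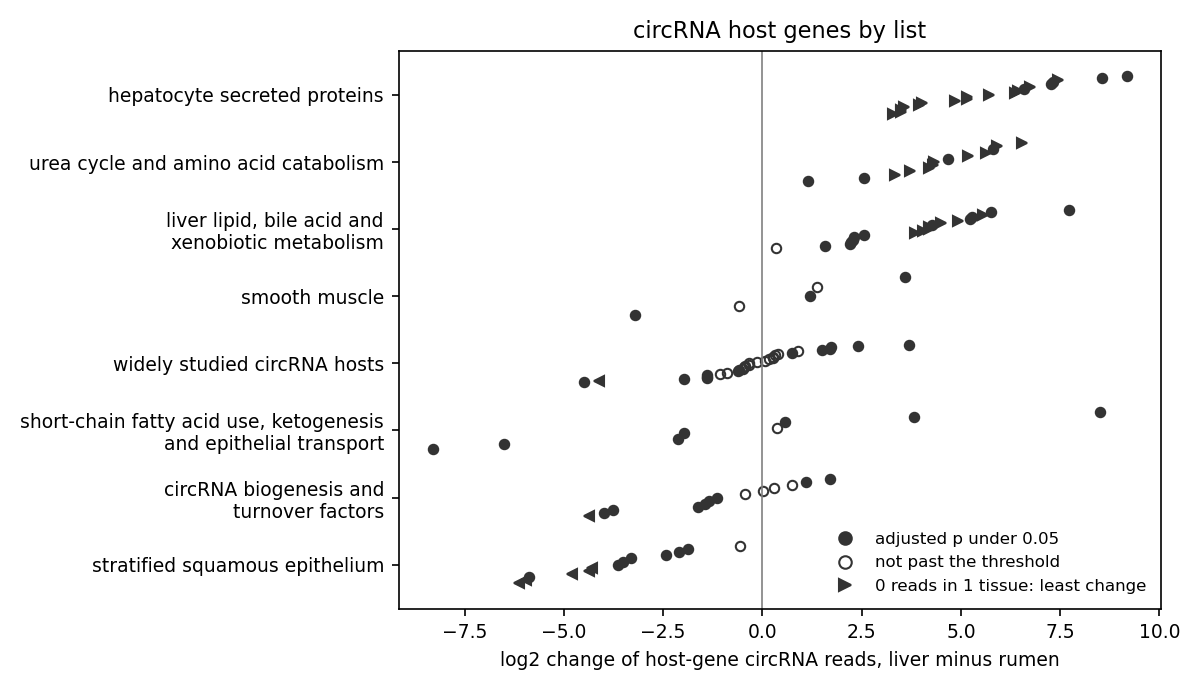
Log2 change, liver minus rumen, of host-gene circRNA reads for the measured members of the 8 tested lists. Each point is a gene, filled where the adjusted p is under 0.05, and triangles mark genes with 0 reads in 1 tissue at their smallest possible change. The 3 liver lists lie above 0 and the squamous list below it, while the other 4 lists spread over both sides.

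With TMM scaling no method effect passed the test of a difference between the tissues. edgeR called 0 of 1842 circRNAs for Ribo-R against R, RTP against R and Ribo-RP against Ribo-R, with 91, 99 and 57 at an unadjusted p under 0.05 and smallest adjusted p of 0.225, 0.220 and 0.632, and DESeq2 called 0 in each. For RTP against R, RLE size factors and BSJ totals alone each called 1, and TMM moved the median interaction of that comparison from -0.08 to -0.20 and that of Ribo-R against R from -0.07 to -0.17. The gene lists, tested in the method comparisons, gave 0 calls in 32 camera tests, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.264, and adjusted p with an estimated correlation was 0.957 or more. The self-contained fry test called 1, the widely studied hosts in rumen Ribo-R against R (adjusted p = 0.0393).

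The most abundant circRNAs were partly shared between the tissues. In liver the 5-exon, 419 nt circRNA of PFKFB1 (chromosome X, 92407499 to 92421831, minus strand) led with 22465 ± 2016 CPM (n = 12), followed by SLC41A2 (chromosome 5, 68474218 to 68485743, 7983 ± 2077), NADK2 (chromosome 20, 38012546 to 38014602, 5737 ± 673), TXNDC11 (chromosome 25, 10399049 to 10418048, 5685 ± 2567) and the deubiquitinase USP3 (chromosome 10, 46480909 to 46485029, 4453 ± 760). In rumen USP3 led with 5200 ± 1106 CPM, before PCNX1 (chromosome 10, 82583563 to 82585269, a single exon of 1707 nt, 4956 ± 928), SMC5 of the SMC5/6 chromosome maintenance complex (chromosome 8, 46417536 to 46429940, 4496 ± 1076), COQ3 of ubiquinone synthesis (chromosome 9, 50387065 to 50399619, 4120 ± 583) and NDST1 of heparan sulfate synthesis (chromosome 7, 61853686 to 61857125, 3883 ± 1014). The rumen Ribo-RTP library gave 3365 CPM for USP3, 5192 for PCNX1, 2884 for SMC5, 3654 for COQ3 and 5865 for NDST1. The liver Ribo library, made without RNase R, had most reads for PFKFB1 (46 reads, 21366 CPM, Poisson interval 15642 to 28499), TXNDC11 (21 reads), SLC41A2 (19), NADK2 (16) and SMC5 (11). It had 2 reads of the ARID1A circRNA (929 CPM) and 7 of the PROX1 circRNA (3251 CPM), single values that have no replicate check.

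Of the 305 circRNAs found in the liver Ribo library with at least 2 reads, most were found again after RNase R. The share with at least 2 reads in any library of a method was 83.9% for R (Wilson interval 79.4 to 87.6%), 86.6% for RTP (82.3 to 89.9%), 92.1% for Ribo-R (88.6 to 94.7%), 90.2% for Ribo-RP (86.3 to 93.0%) and 85.9% for Ribo-RTP (81.55 to 89.4%), over 3 libraries each and 2 for Ribo-RTP. The methods also differ in depth, which was not equalized here. Named after their values were seen, 3 circRNAs (0.984%, 0.335 to 2.85%), of HLTF, CRELD1 and an intron of HNRNPH3, had no read in the other 14 liver libraries.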

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

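The alternative that leaves out both shallowest libraries was chosen only after the result was seen. Of 87 named results, 68 kept their direction and their side of the threshold under all alternatives, and of 2549 alternative values the others are given here or counted. Among named results, other settings ended 35 calls and added 3, and leaving out a library ended 32 calls, added 6 and reversed 1, COL14A1, which ranged from -1.34 without liver Ribo-RP replicate 2 to 0.33 without rumen R replicate 3. Where a filter or a fit of 2 groups changes a count, fewer or more circRNAs are tested and adjusted for; the cause of the other changes was not tested.

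With no filter the calls were 2 for liver Ribo-R against R, 0 for liver RTP against R and 0 for liver Ribo-RP against Ribo-R (unadjusted p under 0.05 in 325, 227 and 195 of 32345). With 10 reads in 3 libraries they were 0, 0 and 0 for liver RTP, Ribo-RP and Ribo-RTP, 7 for rumen Ribo-R, 0 for rumen Ribo-RP, 421 circRNAs and 640 host genes between tissues. DESeq2 gave 0, 0 and 0 for liver RTP, Ribo-RP and Ribo-RTP (unadjusted 52, 24 and 58), 5 for rumen Ribo-R and 0 for rumen Ribo-RP (unadjusted 21). Fits of the 2 compared groups alone gave 4 for liver Ribo-R, 0 for liver RTP and Ribo-RP, and 7 for rumen Ribo-R. RLE size factors and BSJ totals without a scaling factor each gave 1 tissue-dependent circRNA for RTP against R, and fry gave 1 method list. Between tissues, fry gave 6 lists where camera gave 4. For the intronic share, circRNAs with at least 5 reads in 3 libraries gave -0.22 points for Ribo-R minus R (exact permutation, adjusted p = 0.1) and 0.0021 for liver minus rumen (adjusted p = 0.992). The share of detected circRNAs gave -0.34 for Ribo-R minus R (adjusted p = 0.14) and 0.47 for liver minus rumen (adjusted p = 0.0017). For RTP minus R it gave a reversed -0.043.

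With single libraries left out, log2 reads ranged from 0.13 to 0.53 for RTP minus R and 0.12 to 0.32 for liver minus rumen, and log2 detected circRNAs from 0.14 to 0.47 for RTP minus R, -0.13 to 0.014 for Ribo-RP minus Ribo-R and -0.020 to 0.15 for liver minus rumen. At equal reads RTP minus R ranged from -0.041 to 0.053. Intronic points ranged from -0.44 to -0.33 for Ribo-R, -0.041 to 0.34 for RTP, 0.14 to 0.33 for Ribo-RP and 0.22 to 0.41 for liver minus rumen. Calls ranged from 4 to 6 for liver Ribo-R, 0 to 2 for liver RTP, 0 to 2 for liver Ribo-RP, 7 to 13 for rumen Ribo-R, 0 to 1 for rumen Ribo-RP, 881 to 935 circRNAs and 954 to 1014 host genes between tissues. Reads for Ribo-R minus R stayed between 1.14 and 1.39.

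The labels do not say that a replicate number stands for a steer. Deviations of same-numbered libraries correlated between -0.00553 and 0.136 over 26 pairs in liver and 0.0257 and 0.167 over 18 in rumen, above 0.1 in 6 and 10. Pairs with different numbers reached at most 0.0243 in liver and 0.0156 in rumen. All 14 liver and 12 rumen libraries correlated best with their own number, so the numbers may well mark shared samples. If they do, libraries with the same number are not independent, as the main tests take them to be. With the replicate number as a block, calls were 1 for liver Ribo-RP against Ribo-R, 25 for rumen Ribo-R against R (all 14 among them), 930 circRNAs and 1017 host genes. Sign-flip tests of paired differences reached their smallest p, 0.03125, for Ribo-R minus R in reads (1.28), detected circRNAs (1.06), circRNAs at equal reads (0.12) and the intronic share (-0.36), with adjusted p of 0.0938, 0.0938, 0.0938 and 0.0625. They take the pairs of both tissues as independent, although these come from 3 steers. Among named results the block ended PHF3 in liver and ATXN2L and added 1 host gene call, and it changed no other call. In simulation 26.9% to 61.2% of 4-fold changes were recovered in the method comparisons, with 2 or 3 libraries per group, and between tissues, with 12, 83.6% for circRNAs and 89.6% for host genes.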

Other observations

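The splits of the libraries, the tests in other libraries, the test of raw reads and the test of single libraries for the intronic circRNAs were chosen only after the result was seen.

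circRNAs of 1 host gene mostly changed in the same direction between the tissues. Of 160 host genes with at least 2 called circRNAs, 2 held circRNAs of both directions, named after their values were seen, BRWD1 (1.24 and -1.40) and DHRS7, a dehydrogenase (1.42 and -1.90). When directions were shuffled over the called circRNAs, 92.3 genes did on average (81 to 103), and p was 1e-04, the smallest that 10000 shuffles can give. The hypothesis that circRNA choice within a gene differs between the tissues was to be excluded by a number at or below the shuffled one. That bound was wrong, since circRNAs of 1 gene share the level of their host and a shift between them need not turn a direction, so the value of 2 leaves it open. The geometric mean spliced length over circRNA reads was 474.3 nt in the liver Ribo library, against 445.6 ± 2.61 nt in liver R and 458.7 ± 2.86 nt in liver Ribo-R (SD, n = 3 each), and 451.0 ± 17.0 and 468.9 ± 2.01 nt in rumen (n = 3 each), with no test.

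A few circRNAs were lower with rRNA removal before RNase R, with a median log2 change of -2.88 over 9 comparisons of 8 circRNAs such as ARID1A, PROX1 and SATB1. In libraries of the other methods, Ribo-RP minus RTP, all 9 were lower, 6 of them called, with a median of -3.53. Chance in the Ribo-R and R libraries alone does not account for them. Ribo-RP and RTP also differ in tailing, so this was not a comparison of rRNA removal alone. A trend with the genomic distance between junction ends predicts 0.164, which excludes it as the whole cause. Thinning Ribo-R libraries to the depth of R left a median of -3.08, and 8 of 9 calls stayed in over 10 of 20 draws. Thinning leaves the expected CPM as it was, but all 9 also had more raw reads in the shallower R libraries, with a median ratio of 3.89, from 84 against 75 reads (C16H1orf116) to 18 against 0 (FBRS). Fewer reads in R would not by themselves give more raw reads there. But the 9 were picked by their calls, and a fall larger than the difference in depth implies more raw reads in R. The raw reads are therefore not a separate test, and the role of depth stays open here. Capture of these circRNAs by the rRNA removal probes stays open, since no genome sequence was used here. The methods are technical treatments of the same tissues, and no biological explanation was tested.

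Other circRNAs were higher with rRNA removal, with a median of 3.38 over 12 comparisons of 10 circRNAs, or 2.66 with the 5 that had 0 reads in R at their bound, among them LARP1B and ARHGAP5. The other libraries, Ribo-RP minus RTP, gave a median of 1.86, with 11 of 12 higher, 4 of them called, and KIAA2026 at -2.82. Chance in the Ribo-R and R libraries alone does not account for the set. Ribo-RP and RTP also differ in tailing, so this was not a comparison of rRNA removal alone. In liver, with tailing in both, LARP1B stood at 1869 CPM in Ribo-RTP and 883 in RTP libraries. PHF3 stood at 70.2 and 58.5 CPM, from 3 reads each. The trend with distance predicts 0.247, so junction distance is not the whole cause. Thinned libraries gave 3.31, and 7 of 12 calls stayed in over 10 of 20 draws. A kept median was to exclude fewer reads in R, but that bound was wrong, since thinning leaves the expected CPM as it was, and the role of depth stays open here. The cause within the protocols stays open, and no biological explanation was tested.

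The intronic circRNAs of HIP1R and ATXN2L were higher after poly(A) steps in liver. The 3 other tested intronic circRNAs were also higher in each of the 3 comparisons, with medians of 1.73, 1.19 and 0.868, so a rise of all intronic circRNAs may be part of it and cannot be told apart from a change of these 2 with so few members. Short exonic circRNAs, 62 under 200 nt, had medians of at most 0.157, which excludes a rise of all short circles. The call of HIP1R between Ribo-RTP and Ribo-R does not rest on a single library, since the lower of the 2 Ribo-RTP libraries stood at 3.94 times the highest Ribo-R library (counting interval 1.94 to 8.64). For the other 3 calls a single library as the cause stays open. In Ribo-RP libraries the reads of both circRNAs fell from replicate 1 to 3 in liver and in rumen. HIP1R reads in RTP and in Ribo-R libraries followed other replicate orders, each shared by the tissues. A factor tied to the replicate number therefore stays open for all calls of both circRNAs. The same ratio was 1.36 (0.554 to 3.63) for HIP1R between RTP and R, 0.186 (0.0200 to 0.851) between Ribo-RP and Ribo-R, and 2.81 (0.226 to 147.5) for ATXN2L. HIP1R ended between RTP and R without liver RTP replicate 3 (1.37), R replicate 2 (2.06) or R replicate 3 (2.01), and between Ribo-RP and Ribo-R without liver Ribo-RP replicate 1 (0.69), Ribo-R replicate 2 (1.80) or Ribo-R replicate 3 (2.22). ATXN2L ended without liver Ribo-R replicates 1, 2 or 3 (3.25, 3.27 and 3.30) or Ribo-RP replicates 1 or 2 (2.43 and 3.40). In rumen HIP1R stood at -0.47 for RTP against R and 1.09 for Ribo-RP against Ribo-R, and neither passed (edgeR's quasi-likelihood test, adjusted p of 0.909 and 0.999).

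Of 100 splits of the 24 libraries, only the real one gave as many calls between tissues, 935 circRNAs (highest other 0) and 1010 host genes (highest other 1). This argues against a chance sorting of single libraries. The splits move single libraries, which come from 3 steers, so chance between steers is not excluded. For the list tests with the preset correlation, 53 of 100 splits gave 4 or more lists (real 4, highest other 5), so chance cannot be excluded. A split with unequal numbers of liver and rumen libraries on its sides keeps part of the tissue difference. How far this raised the count was not tested. With an estimated correlation only the real split gave 4 lists (highest other 1), with the same limit on steers. For the method lists (100 splits, real 0, highest other 2) and tissue-dependent method effects (100 splits in each of 3 comparisons, real 0, highest other 27, 3 and 4) every split is as large as a real count of 0, so the splits say nothing about chance. Methods were shuffled in each tissue on its own, so a split that swaps them in 1 tissue can turn a shared method effect into a tissue-dependent one. Whether the split with 27 calls for Ribo-R against R was of that kind was not examined. For the within-tissue method comparisons the 10 splits are too few for a share under 0.05. There the real and the highest other counts were 7 and 0 for liver Ribo-R against R (1 split as large), 1 and 1 for liver RTP against R (3), 2 and 1 for liver Ribo-RP against Ribo-R (1), 14 and 0 for rumen Ribo-R against R (1), 0 and 4 for rumen RTP against R (10, as for any count of 0), and 1 and 1 for rumen Ribo-RP against Ribo-R (2).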
